A study of Homo sapiens with 6 samples.

How the data were processed

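Human U-937 cells expressing Cas9 received sgMETTL1.3 or the control guide sgNS, and RNA libraries were made from 3 replicates of each. Per the labels' protocols, libraries came from 300 ng of total RNA with an mRNA kit and ERCC spike-ins were used. The amount added and the step are not given in the sources used here. Had they been added in proportion to the total RNA, the spike-in scale would measure mRNA per amount of total RNA, and nothing in the labels ties it to a number of cells. For every library the labels give harvest at day 8 to 10, blasticidin at 10 µg/ml and hygromycin at 200 µg/ml. They name both QIAzol and TRIZOL for extraction, and give a wider range of time for selection than for harvest.

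Per the submitters' processing notes, the tools were cutadapt, STAR and RSEM with the builds GRCh38 and hg38, and versions, annotation and strand setting are not given in the sources used here. The deposited signal values are TPM, rounded to a step of 0.01, multiplied by 1 factor per library so that the 92 spike-in rows sum to 38252 in each library; this was read from the values. The steps of low values are rounding and not reads, so the depth is unknown and no counting interval is given. Spike-ins made up 3.22 ± 0.144% of the total in sgNS and 4.12 ± 0.440% in sgMETTL1.3 (SD, n = 3; exact permutation p = 0.1), and the 18S and 28S rows 5.68 ± 0.238% and 5.24 ± 0.813% (exact permutation p = 0.4). Of 26902 rows, 28 bore names turned into dates; 17 of these were tested and none is named. Of 949 list genes, 41 had no matching row used here.

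The design had been written for counts, with a branch for TPM, and the TPM branch was used. The 12449 genes with a value of at least 1 in at least 3 of 6 samples were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (trend and robust), without a block and with Benjamini-Hochberg adjustment at 0.05; spike-ins were left out. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The 37 lists, the tests, the rule for named genes and the first set of alternatives were fixed before the data were examined. Coordinates and GC content came from GENCODE release 29 (GRCh38), and 94% of tested genes had a GC value.

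Named genes were METTL1 and WDR4, the 12 highest and 12 lowest log2 fold changes among called genes whose groups did not overlap and whose higher mean was at least 5, the 5 smallest p in each direction, and up to 4 members with the smallest p of each list. Genes without a symbol and pseudogenes were left out of the ranking, and a few genes that the rule selects are not reported here.

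The fit was tested on simulated data with independent genes, using the means and spreads of the 12449 genes of this comparison with 200 changed. It called 42% of genes changed by 0.5 on the log2 scale and 87% of those changed by 1, with 15 unchanged genes called. A list shifted by 0.5 was called, as were 0 of 30 other lists. The simulation has no correlation between genes, so it does not test the preset correlation. It also has no shift shared by a library, and far fewer changed genes than the 797 higher and 6142 lower called in the data. The adjusted threshold was therefore stricter in it, and its percentages do not give the power of the real comparison.

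Alternatives were other scalings, filters, pseudocounts, a fit without trend, a replicate block and each library left out. Those chosen after seeing the data were the values as TPM, a median of spike-in ratios, a GC correction, the GC correction as TPM, and TPM without sgMETTL1.3 replicate 1. The direction of a list under an alternative was taken from the set test; the sign of its median was tried as a second rule after the outcome under the first was known, and the first was kept.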

Results

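Poly(A)-selected RNA was sequenced from U-937 cells, a human myeloid leukemia line with monocytic features, after lentiviral delivery of a guide RNA against METTL1 (sgMETTL1.3) or a control guide (sgNS) into a Cas9-expressing clone. METTL1 is the catalytic subunit of the enzyme that places N7-methylguanosine on tRNA, and WDR4 is its partner subunit. Each group held 3 libraries, and the comparison addressed how this guide against METTL1 changes gene expression in these cells. No other METTL1 guide and no rescue are among the libraries, so other effects of the guide cannot be told apart from loss of METTL1. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The values were TPM scaled to ERCC spike-ins, synthetic RNAs added at an amount and step that the labels do not give, and the read depth behind them is unknown. The libraries listed between 12134 and 12505 genes at a value of at least 1.

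METTL1 transcript was lower in each sgMETTL1.3 library than in any control. The control libraries had METTL1 values of 19.7, 22.0 and 20.3, and the sgMETTL1.3 libraries 8.28, 5.94 and 7.42. The means were 20.7 ± 1.18 and 7.22 ± 1.19 (SD, n = 3), a log2 fold change of -1.41 (SE 0.131, limma adjusted p = 2.41e-06). METTL1 lies on the minus strand of chromosome 12 at positions 57768471 to 57772793 (GRCh38), and its 3′ end overlaps CYP27B1, so reads in the overlap could be assigned to either gene. Its other end overlaps METTL21B on the opposite strand, and the strand setting of the counting is not given. WDR4, on chromosome 21 at 42843094 to 42879568, fell from 26.2 ± 1.65 to 11.4 ± 3.21 (SD, n = 3), a log2 fold change of -1.16 (limma adjusted p = 0.000178). As TPM, the log2 fold changes were smaller in size, at -1.09 for METTL1 and -0.83 for WDR4. Among the 8 tested genes of N7-methylguanosine enzymes and their partners, 3 fell, none rose and 5 did not pass the test (3 fell adjusted over the list alone), while 4 rose and 2 fell as TPM. RNMT, the mRNA cap methyltransferase, was the third that fell (log2 fold change -0.42), and it did not pass as TPM (-0.08). CMTR1, a cap ribose methyltransferase, had a log2 fold change of -0.14 without passing, and rose as TPM (0.20).

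The chemokine genes CXCL8, CCL2 and CCL7 and the lysozyme gene LYZ were among the 12 lowest log2 fold changes. CXCL8, a neutrophil-attracting chemokine, fell from 106 ± 5.48 to 11.7 ± 1.38 (SD, n = 3), a log2 fold change of -3.08 (limma adjusted p = 6.66e-09). Among the monocyte chemokines, CCL2 fell from 337, 362 and 360 in the control libraries to 58.9, 57.7 and 68.0 in the sgMETTL1.3 libraries, and CCL7 fell with a log2 fold change of -2.44. LYZ, which encodes lysozyme, fell from 404 ± 16.3 to 72.1 ± 7.48 (SD, n = 3). With log2 fold changes in parentheses here and in what follows, ME2, the mitochondrial malic enzyme, fell (-2.56), and the phospholipid transporter ATP8B4 fell (-2.51). NXT2, DCSTAMP, SEC13, NME1 and PSME3 were also among the 12 lowest genes, with log2 fold changes from -2.49 for NXT2 to -2.13 for PSME3. NME1 overlaps the NME1-NME2 read-through locus, so its reads could be shared.

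C1QA and HMOX1 were among the 12 highest log2 fold changes. C1QA, a complement component made by macrophages, rose from 6.26 ± 0.0478 to 31.0 ± 6.68 (SD, n = 3), a log2 fold change of 2.12 (limma adjusted p = 2.76e-07). HMOX1, which encodes heme oxygenase, rose from 35.9 ± 0.385 to 118 ± 24.6 (SD, n = 3). Both genes were highest in sgMETTL1.3 replicate 1, a library that stood apart by GC content, as described below. After GC correction the log2 fold change was 1.94 for C1QA, and 1.54 for HMOX1 against 1.67 before. SLC26A11, CYP4F12, ITLN1, SLCO2B1, SNORD3A, FBXO32 and ADGRE3 rose with log2 fold changes from 1.95 for SLC26A11 to 1.71 for ADGRE3. The small RNAs SCARNA26A and RNU6ATAC were listed at 0 in all 3 controls. Their values in the sgMETTL1.3 libraries were 6.77, 27.5 and 26.0 for SCARNA26A and 7.19, 17.9 and 24.0 for RNU6ATAC, and no fold is given. The libraries were poly(A)-selected and the depth is unknown, so the reads behind these values and behind the 0 in controls cannot be given. With the controls at 0, leaving out any sgMETTL1.3 library put both genes below the filter, so neither was tested in those fits.

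**Figure D1:**
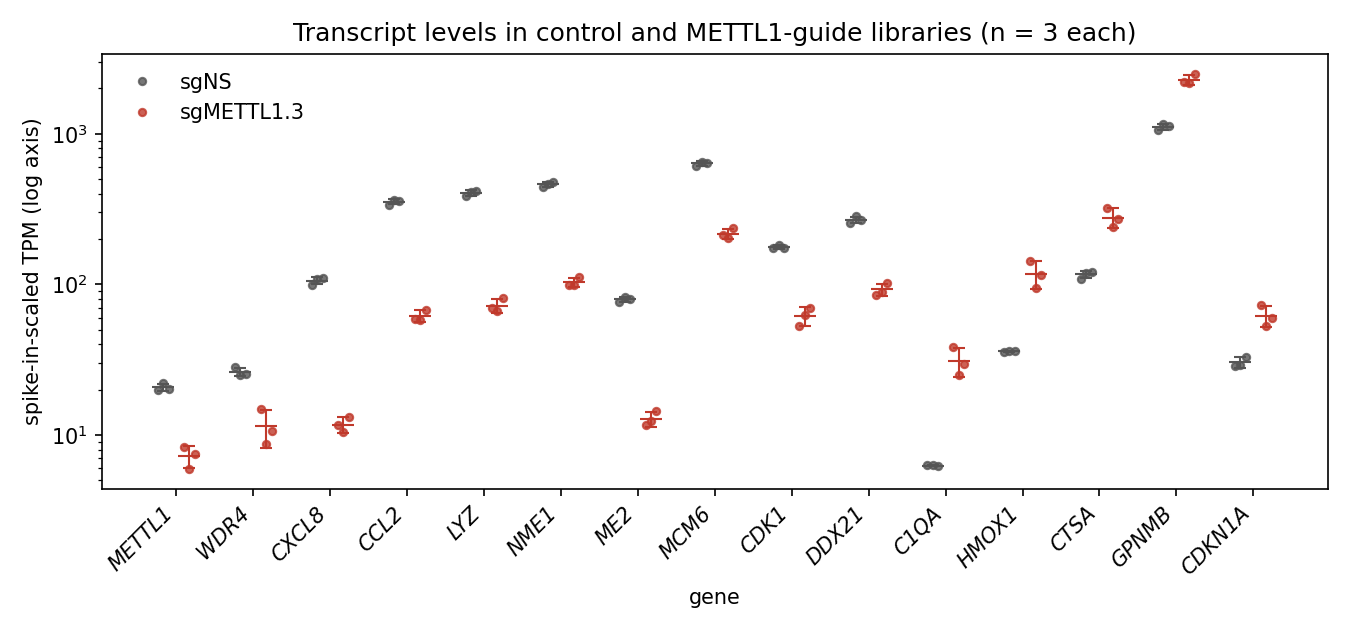
Spike-in-scaled TPM (log axis) of 15 named genes in 3 sgNS and 3 sgMETTL1.3 libraries; points are libraries, horizontal marks are means and bars are SD. METTL1, WDR4 and the genes from CXCL8 to DDX21 lie lower in every sgMETTL1.3 library than in every control, and the genes from C1QA to CDKN1A lie higher.

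Most changed genes were lower on the spike-in scale. Of 12449 genes tested, 797 rose, 6142 fell and 5510 did not pass, and 57 rose and 844 fell by at least 2-fold, against 236 and 221 as TPM. The median log2 fold change of all tested genes was -0.32. As TPM, with the spike-in factor undone, 3021 genes rose and 3295 fell, the median was 0.00, and the increases made up 47.8% of the calls in place of 11.5%. Of the 12365 genes tested under both scalings, 797 rose and 3294 fell in both, and 0 were called in opposite directions. Calls opposite to the spike-in scale did occur under other alternatives. They numbered 25 with quantile normalization, 257 as TPM with GC correction and 339 as TPM without sgMETTL1.3 replicate 1. The spike-in factor averaged 1.19 ± 0.0518 in controls and 0.935 ± 0.0973 in sgMETTL1.3 libraries (SD, n = 3), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give. On the spike-in scale, values of 62.1% of genes did not overlap between the groups. For a single gene, chance gives 10%, but the factor of a library moves all its genes together. The factors themselves did not overlap, at 1.13 to 1.23 in controls and 0.832 to 1.03 in sgMETTL1.3 libraries. The 10% is therefore no yardstick for the 62.1%.

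The library sgMETTL1.3 replicate 1 stood apart from the rest of its group. Its deviation from the other 2 libraries followed transcript GC content across genes (Spearman 0.848, genes are not independent replicates), and its spike-in ratios spread with an SD of 0.289 on the log2 scale, against 0.083 or less in the other libraries. Without it, 790 genes rose and 7538 fell. That fit pooled the spread fully across most genes (median prior degrees of freedom infinite, against 9.14 with all libraries). Its counts are therefore not directly comparable with those of the main fit.

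**Figure D2:**
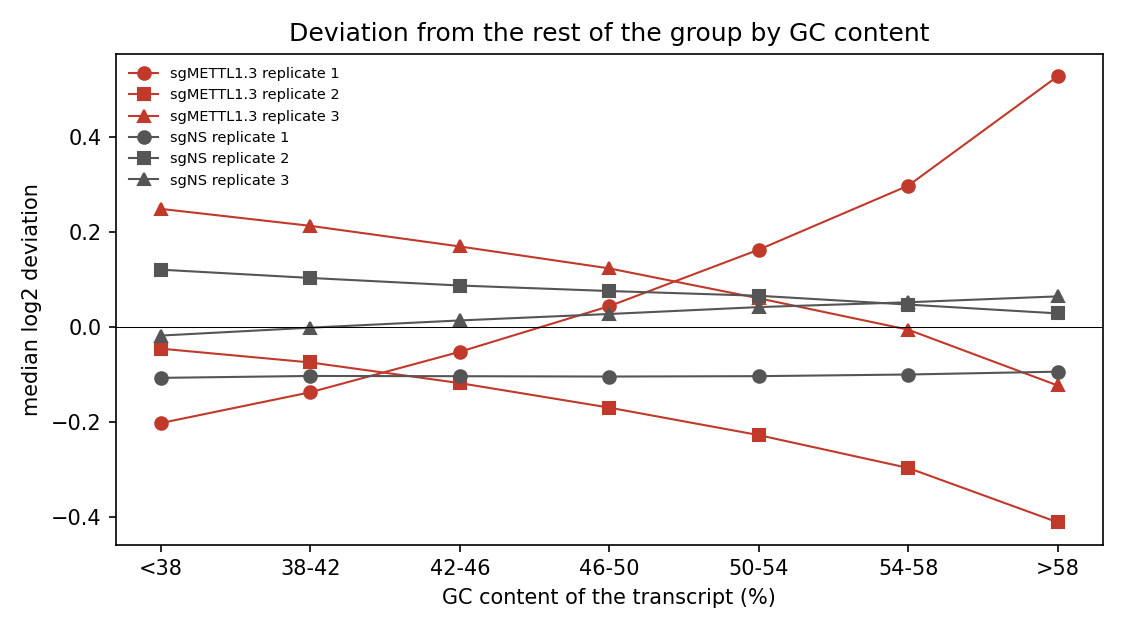
Median log2 deviation of each library from the mean of the other 2 libraries of its group (vertical axis) in bins of transcript GC content in percent (horizontal axis). The line of sgMETTL1.3 replicate 1 climbs from -0.20 to 0.53, and the lines of the other sgMETTL1.3 libraries fall because their reference includes it.

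Most tested genes of ribosome biogenesis, MYC targets and the cell cycle fell on the spike-in scale. The set test called these 4 lists lower than other genes at the preset correlation, and none of them with an estimated correlation (adjusted p = 0.935 for each). Ribosome biogenesis genes had 35 of 36 members lower (36 adjusted over the list alone; 35 as TPM) and a median log2 fold change of -0.93, with DDX21, an RNA helicase of the nucleolus, falling (-1.53), GNL3 (-1.32), WDR12 (-1.22) and NOLC1 (-1.17). Of 25 genes of MYC and its targets, 24 fell (24 adjusted over the list alone), and 22 fell and 1 rose as TPM, with a median of -1.11. ODC1, the first enzyme of polyamine synthesis, fell (-1.27) and LDHA, which encodes lactate dehydrogenase, (-1.19). MYC itself, chosen after its values were seen, fell from 278 ± 9.63 to 94.1 ± 19.1 (SD, n = 3). Of 35 genes of G1/S and DNA replication, 30 fell (30 adjusted over the list alone), and 28 fell and 2 rose as TPM, with a median of -0.83. MCM6, a subunit of the replicative helicase, fell (-1.55), TYMS, thymidylate synthase, (-1.43), GINS1 (-1.49) and RRM1 (-1.20). Of 35 genes of G2/M and mitosis, 30 fell and 1 rose (31 and 1 adjusted over the list alone), against 17 and 2 as TPM, with CDK1 falling (-1.52), MAD2L1 (-1.23), AURKA (-1.04) and BUB1 (-0.98).

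Lists of mitochondrial translation, translation factors, RNA modification enzymes, aminoacyl-tRNA synthetases, glycolysis and heat shock genes were also called lower than other genes at the preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.935 for each). Of 32 genes of the mitochondrial ribosome and translation, 31 fell (31 adjusted over the list alone), and 23 as TPM, with a median of -0.72. MRPL3 fell (-1.65) and MTIF2, a mitochondrial initiation factor, (-1.23). Of 35 translation initiation and elongation factors, 26 fell (27 fell and 1 rose adjusted over the list alone), among them EIF2B5 (-1.63) and EIF4E, the cap-binding factor, (-1.13), and 19 of 36 fell and 6 rose as TPM. Other RNA modification enzymes had 34 of 39 members lower (35 adjusted over the list alone), and 25 as TPM, with PUS7, a pseudouridine synthase, falling (-1.43) and ADAT2, a tRNA adenosine deaminase subunit, (-1.20). Cytosolic aminoacyl-tRNA synthetases had 15 of 21 members lower (16 adjusted over the list alone), and 12 lower and 4 higher as TPM, with FARSB falling (-1.37) and DARS (-0.99), and this list was not called as TPM (adjusted p = 0.138). Of 22 glycolysis genes, 16 fell (16 adjusted over the list alone), and 11 fell and 2 rose as TPM, with SLC2A1, a glucose transporter, falling (-1.39) and TPI1 (-1.11). Of 16 heat shock genes, 12 fell (12 adjusted over the list alone), and 8 fell and 2 rose as TPM, with HSP90AA1 falling (-1.22) and HSPD1 (-1.05).

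The list of lysosome and autophagy genes was called higher than other genes at the preset correlation. The call did not hold with an estimated correlation (adjusted p = 0.935, and 0.142 as TPM). Of 32 members, 12 rose and 8 fell (13 and 8 adjusted over the list alone), and their median was 0.23. The median was 0.09 without sgMETTL1.3 replicate 1 and 0.14 after GC correction, and 23 rose and 4 fell as TPM. CTSA and CTSB, lysosomal proteases, rose from 116 ± 6.43 to 277 ± 41.7 and from 353 ± 14.6 to 677 ± 68.2 (SD, n = 3), while the autophagosome gene MAP1LC3B fell (-1.08) and its relative GABARAPL1 rose with a log2 fold change of 0.84. NRF2 oxidative stress targets had 7 of 19 members higher and 7 lower (7 and 8 adjusted over the list alone), and 10 higher and 3 lower as TPM. HMOX1 and NQO1 rose, while SRXN1 fell (-1.07) and ABCC1 (-0.75). ATF4 and amino acid response targets had 6 of 30 higher and 12 lower (6 and 13 adjusted over the list alone), and 13 higher and 3 lower as TPM. NUPR1, SESN2 and PPP1R15A, stress-induced genes, rose with log2 fold changes of 1.37, 1.08 and 0.86, and the amino acid transporter SLC38A2 fell (-0.81). Both lists were called higher relative to other genes, although their medians were -0.06 for NRF2 targets and -0.09 for ATF4 targets, and both medians were above 0 as TPM (0.28 and 0.24). Neither call held with an estimated correlation (adjusted p = 0.935 for both), and without sgMETTL1.3 replicate 1 the medians were -0.12 and -0.23.

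**Figure D3:**
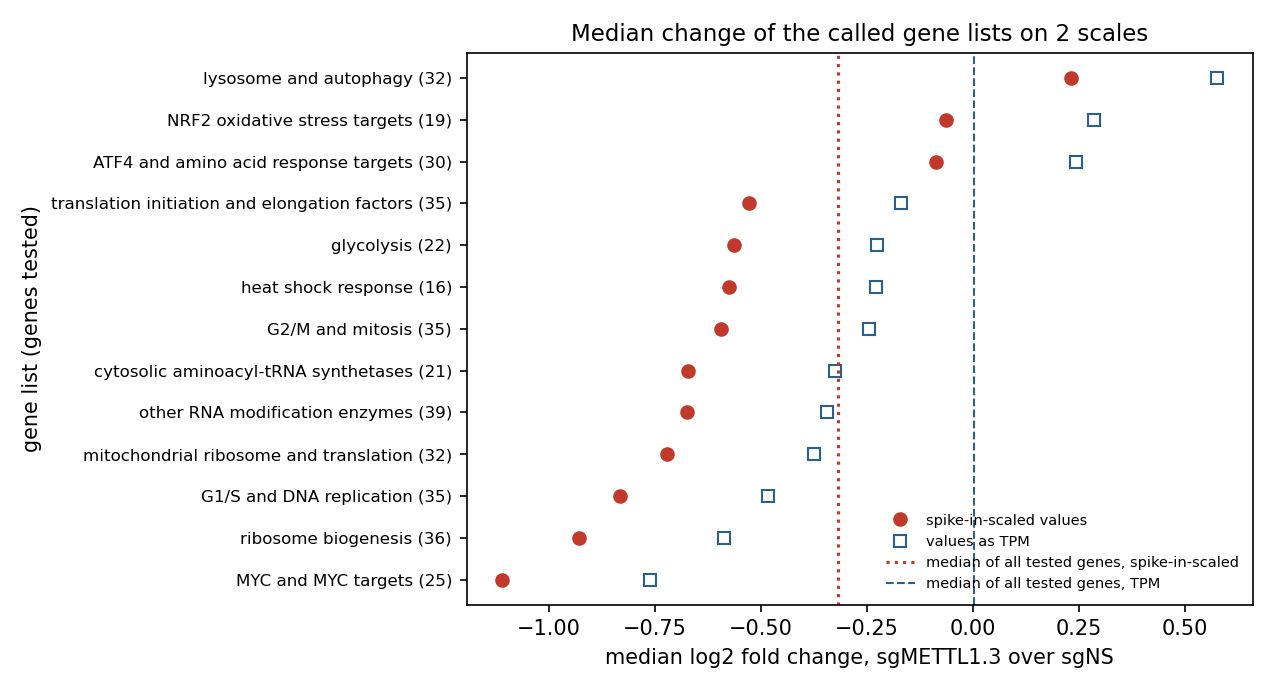
Median log2 fold change (horizontal axis) of the 13 called gene lists (vertical axis, genes tested in parentheses), spike-in-scaled (filled circles) and as TPM (open squares); vertical lines are the medians of all tested genes. MYC targets lie lowest at -1.11 and lysosome genes highest at 0.23 on the spike-in scale, and the medians of NRF2 and ATF4 targets change sign as TPM.

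The set test called 13 of the 31 testable lists with limma's camera at a preset correlation, 10 lower and 3 higher. With an estimated correlation it called 0 of them, with adjusted p = 0.935 for every list. Other splits of the same 6 libraries called up to 10 lists at the preset correlation, but each keeps part of the guide difference.

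Lists that were not called also held members that changed, and several of their counts shifted with the scaling. Among all tested genes, 797 of 12449 rose and 6142 fell, against 3021 and 3295 of 12404 as TPM. Cytosolic ribosomal proteins had 48 of 76 members lower and none higher, among them RPL38, which fell (-1.59), but 19 higher and 13 lower as TPM. Monocyte and macrophage genes had 6 of 32 higher and 17 lower, and 11 higher and 15 lower as TPM; GPNMB rose from 1113 ± 53.1 to 2285 ± 188 (SD, n = 3), and the pattern receptors CLEC7A (-1.38) and TLR2 (-1.47) fell. Neutrophil granule genes had 9 of 12 lower and 1 higher, and 7 lower and 3 higher as TPM, with CTSG, cathepsin G, falling (-2.01). This list was called without sgMETTL1.3 replicate 1 (adjusted p = 0.000971, and 0.913 with an estimated correlation), also as TPM (adjusted p = 0.0368, and 0.278 with an estimated correlation). Inflammatory cytokine genes had 15 of 24 lower and 1 higher, and 7 lower and 5 higher as TPM; IL1RN fell (-0.93). Type I interferon genes had 10 of 26 lower and 5 higher, and 4 lower and 14 higher as TPM, with MX2 falling (-0.75) and IFIT2 rising with a log2 fold change of 0.69. This list was called higher than other genes after GC correction (adjusted p = 0.0106, and 0.954 with an estimated correlation) and without sgMETTL1.3 replicate 1 (adjusted p = 0.0374, and 0.913 with an estimated correlation), and under 3 other alternatives. Among p53 targets and cyclin kinase inhibitors, 14 of 26 fell and 3 rose, 8 fell and 7 rose as TPM, and CDKN1A, which encodes p21, rose from 30.3 ± 2.45 to 61.9 ± 10.2 (SD, n = 3) while FAS fell (-1.08). Apoptosis regulators had 11 of 23 lower and 4 higher, and 6 lower and 7 higher as TPM, with MCL1 falling (-1.03) and BMF rising with a log2 fold change of 1.10. Myeloid transcription factors had 12 of 24 lower and 1 higher, and 10 lower and 4 higher as TPM, and MYB fell from 239 ± 11.9 to 96.4 ± 6.47 (SD, n = 3).

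Metabolic and other lists that were not called also held lower members, as did 6142 of all 12449 tested genes on the spike-in scale. Shares near or below that one, such as those of cholesterol synthesis and histones, are no result about the list. Cholesterol synthesis had 12 of 23 lower, and 6 lower and 6 higher as TPM, with INSIG1 falling (-1.84) and SQLE (-1.39). Fatty acid synthesis had 8 of 12 lower, against 6 lower and 2 higher as TPM, and FADS1 fell (-0.94). Nuclear-encoded oxidative phosphorylation had 36 of 53 lower, against 12 lower and 8 higher as TPM, and NDUFB5 fell (-0.86). Hypoxia targets had 9 of 16 lower and 2 higher, and 5 lower and 5 higher as TPM, with ERO1A falling (-1.72). Unfolded protein response genes had 7 of 20 lower and 1 higher, against 4 lower and 9 higher as TPM, and the chaperone gene CALR fell (-1.21). Replication-dependent histones had 7 of 17 lower and 3 higher, and antigen presentation by MHC class I had 3 of 9 lower and 1 higher, the latter being B2M with a log2 fold change of 0.25. As TPM these were 3 lower and 5 higher for histones and 1 lower and 4 higher for MHC class I. Neighbours of METTL1 on chromosome 12 had 4 of 9 lower, and 2 lower and 3 higher as TPM, among them METTL21B, which fell (-0.77), and CDK4, which fell (-0.46) and did not pass as TPM. Of 5 B cell markers tested, PAX5 fell (-0.76) and the others did not pass. Markers of T and natural killer cells had 4 tested genes, of erythroid and megakaryocytic cells 3, of fibroblasts and endothelium 4, of epithelial and HEK293-type cells 1, and MHC class II genes 2, too few for the set test.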

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

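METTL1 stayed lower and past the threshold under all 19 alternatives, from -1.50 to -1.29 over the fits that left out 1 library each. It was nearer 0 with median ratios (-1.11), quantiles (-1.10), values as TPM (-1.09) and a pseudocount of 5 (-1.08). Of 136 other named genes, 124 kept direction and side wherever tested, but the 136 were picked by fold or p in this fit. As TPM, 2828 of all lower genes lost their call and 2199 uncalled genes rose. SCARNA26A and RNU6ATAC missed the filter with any sgMETTL1.3 library left out. Scalings not tied to the spike-ins changed the counts, since they move the median of all genes to about 0. The values as TPM, the GC correction, both together and TPM with 1 library left out were chosen after seeing the data. Genes higher numbered 2869 with median-ratio rescaling, 2975 with quantile normalization, 3021 as TPM, 3789 as TPM with GC correction, 4231 as TPM without sgMETTL1.3 replicate 1, and 510 with a mean of at least 5, where fewer genes were tested. Genes lower numbered 3603, 3227 and 3295 with the first 3 of these. Genes changed at least 2-fold numbered 473, 455, 457, 357 and 354 with the first 5, and 498 with a pseudocount of 5, which shrinks the folds of low genes. Leaving out 1 library gave 534 to 1037 genes higher (534 without sgMETTL1.3 replicate 3), 4880 to 7538 lower, 795 to 1074 changed at least 2-fold and 11 to 15 lists. The 7538 came from the fit without sgMETTL1.3 replicate 1, which pooled the spread across genes. Glycolysis and heat shock genes lost their call without sgMETTL1.3 replicate 3 and with a mean of at least 5, heat shock genes also with quantiles and as TPM with GC correction, G2/M genes and translation factors with quantiles, ATF4 and NRF2 targets with no filter, and aminoacyl-tRNA synthetases with a mean of at least 5 and under every scaling not tied to the spike-ins. Lists gained with camera were type I interferon genes (in 5 settings, 2 of them without 1 library), neutrophil granule genes (with the replicate block, adjusted p = 0.013, without sgMETTL1.3 replicate 1 and as TPM without it), ribosomal proteins, fatty acid synthesis and oxidative phosphorylation with no filter, the unfolded protein response as TPM without sgMETTL1.3 replicate 1, and histones with a mean of at least 5 and without sgNS replicate 3. None of these calls held with an estimated correlation in the same fit (adjusted p from 0.275 to 0.99). The lists called numbered 0 with an estimated correlation and 22 with fry, which does not compare a list with other genes. Replicate numbers did not pair the samples: same-numbered deviations correlated at -0.014, 0.005 and -0.039. The replicate block gave 814 higher, 5861 lower, 907 changed at least 2-fold, 14 lists and a METTL1 value of -1.41. The planned spike-in scaling equals the deposited scale, and count-based tests were not run because the values are not counts. What the unknown read depth limits could not be given.

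Among named genes the direction reversed for CMTR1 (0.18 with median ratios, 0.25 with quantiles, 0.20 as TPM, 0.14 as TPM with GC correction, 0.19 as TPM without sgMETTL1.3 replicate 1), EBF1 (0.087 with median ratios, 0.10 as TPM, 0.23 as TPM with GC correction, 0.053 as TPM without that library), RNMT (0.048 and 0.051 under the last 2) and ERAP2 (0.10 and 0.068 under the last 2). The cause was not tested beyond the scale shift.

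No called list reversed in the direction of its set test, and 33 of 583 pairs of a list and a setting did, all in uncalled lists. With median ratios their medians were 0.19 for N7-methylguanosine enzymes, -0.071 for p53 targets and -0.26 for monocyte genes. With quantiles they were 0.28, -0.029 and -0.14 for these, -0.030 for B cell markers, 0.0014 for oxidative phosphorylation, 0.0085 for ribosomal proteins and 0.059 for cholesterol synthesis. As TPM they were 0.21 for N7-methylguanosine enzymes, -0.049 for p53 targets, -0.24 for monocyte genes and 0.024 for ribosomal proteins. As TPM with GC correction they were 0.093 for N7-methylguanosine enzymes, -0.21 for monocyte genes, 0.0060 for ribosomal proteins and 0.033 for hypoxia targets. As TPM without sgMETTL1.3 replicate 1 they were 0.17, -0.16, 0.013 and 0.036 for these and 0.032 for cholesterol synthesis. With no filter they were -0.11 for monocyte genes, -0.12 for MHC class I, -0.17 for the unfolded protein response, -0.23 for apoptosis regulators, -0.26 for METTL1 neighbours and -0.37 for p53 targets. With a mean of at least 5 they were -0.13 for N7-methylguanosine enzymes and -0.37 for myeloid transcription factors. With the replicate block the value was -0.53 for monocyte genes, and over the fits that left out 1 library it ran from -0.62 to -0.45, reversed only at -0.57 without sgMETTL1.3 replicate 1. The cause was not tested. Judged by the sign of the median instead, a rule tried after these outcomes were seen, 66 pairs reversed, 13 of them in 2 called lists: ATF4 targets in 6 settings (0.032 to 0.26) and NRF2 targets in 7 (0.0036 to 0.31).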

Other observations

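The tests of GC content, spike-in ratios, ribosomal RNA share, spike-in factors, neighbouring genes and symbol families were chosen after the main results were seen, as was the use made here of the median from the planned fit without sgMETTL1.3 replicate 1. Gene families grouped by the stem of their symbol, 189 in all with at least 8 tested members, held further groups. Zinc finger genes (ZNF), mostly transcriptional repressors, had 36 of 325 members higher and 65 lower with a median log2 fold change of -0.07, and stood higher than other genes (camera adjusted p = 1.32e-05, and 0.989 with an estimated correlation); as TPM, 132 were higher and 15 lower. Nucleoporins (NUP) had 19 of 20 lower with a median of -0.88, chaperonin subunits (CCT) 8 of 8 with -0.99, outer mitochondrial membrane import genes (TOMM) 9 of 9 with -0.76, and MCM genes 10 of 10 with -0.83. As TPM, 16, 7, 8 and 10 of these were still called lower. In all, 9 families were called at the preset correlation, and the estimated correlation gave adjusted p = 0.989 for each of those named here.

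The library sgMETTL1.3 replicate 1 differed from the other libraries of its group. GC content bias of that library may account for it, since its deviation followed transcript GC content at Spearman 0.848 across genes, against at most 0.35 in size in a control library. A difference of the cells in that culture as the whole cause is argued against by the spike-ins, which no cell makes: their log2 ratios had an SD of 0.289 there and at most 0.083 in the other sgMETTL1.3 libraries.

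Most tested genes were lower on the spike-in scale. The GC-biased library is argued against as the whole cause, since the median log2 fold change was -0.37 without it and -0.32 with it. Spike-in amounts that differed between libraries could give the same pattern and cannot be told apart from a lower mRNA share of total RNA in sgMETTL1.3 cells, since no measurement used here gives the amount added apart from the spike-in reads themselves. A permutation test of the factors (exact p = 0.1) could not decide this, as 3 against 3 can give no smaller p. A larger share of ribosomal RNA also stays open: the 18S and 28S share differed by -0.445 percentage points, within its spread, and those rows after poly(A) selection do not measure ribosomal RNA in the input.

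The lists of MYC targets, ribosome biogenesis and replication were called lower than other genes at the preset correlation, and the lysosome list higher. GC content bias as the whole cause is argued against. On the spike-in scale, 12 of the 12 lists called on both scales were still called after the GC correction. As TPM, the GC correction left 11 lists called, and heat shock genes lost their call. Correlation between genes stays open for the set test, as no list was called with an estimated correlation. No biological explanation was tested.

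Large deletions at the cut site may lower neighbouring genes. The 62 tested genes within 2 Mb of METTL1 had a median log2 fold change of 0.00882 relative to all genes, at the 60.1 percentile of 10000 random sets of that size, which argues against a loss of most genes in that window. Deletions that reach only the nearest genes stay open: the 9 tested neighbours in the fixed list had a median of 0.0632 relative to all genes, but METTL21B, TSFM, CDK4 and CYP27B1 lay below the median of all genes.

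The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split was the 1 of 10 with the highest counts. It gave 797 genes higher and 6142 lower, and no other split gave more than 3 in either direction. In the other splits the guide difference adds to the spread within each side, which lowers their gene counts by construction. The real split also gave 901 genes changed at least 2-fold against at most 4, and 13 lists against at most 10. Every other split mixes the guides unequally, so part of the guide difference stays in its list calls. Those calls therefore give no error rate for the preset correlation.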
